A study of Homo sapiens with 24 samples.

How the data were processed

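The series holds 24 arrays of RNA from the human lung cancer lines A549 and Calu-6, cultured in RPMI medium at 37 degrees, with 3 arrays for each of 8 groups: untreated cells and TSC at 0.0005, 0.001 and 0.003 puffs/ml in each line. Per the labels, RNA was isolated with an RNeasy kit and labelled by the Affymetrix biotin protocol. The authors deposited log2 values made with RMA, whose version is not given in the sources used here. Each probe set's median over the 24 arrays was 0 in all 54675 probe sets, so the table gives changes relative to that median and no levels. The authors also deposited 2 lists of regulated probe sets, 1 per line, with the fold change of each dose against control as a ratio of at least 1 and its direction, per the file headers. Per the footers of these lists, a probe set was kept at a one-way ANOVA p of at most 0.05 over the conditions of the line and a change of at least 2-fold at 1 or more doses. Differences of group means in the table matched the signed log2 of the deposited ratios within 4.25e-07 in A549 and 2.28e-07 in Calu-6.

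The 62 AFFX control probe sets were set apart, and the other 54613 were tested without a filter. No table pairing all probe sets with genes was used, so tests and counts are per probe set, and names come from the deposited lists alone. Of the named probe sets tested, 306 had 1 symbol, for 244 symbols, of which 214 were current in a RefSeq table, 22 were found there as synonyms and 8 were not found. Symbols are printed as the lists give them. No coordinates are given, since the sources used here give no genome build.

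Each line was fitted apart with limma 3.58.1 in R 4.3.3, over its 12 arrays in 4 groups (8 residual degrees of freedom), with lmFit and eBayes. Contrasts were each dose minus control and a slope on dose. The difference between the responses of the lines and the difference between untreated lines came from a fit of all 24 arrays (16 residual degrees of freedom). Tests were two-sided, and p values were adjusted by the method of Benjamini and Hochberg over all probe sets of a contrast, with a threshold of 0.05. The comparison of untreated lines also asked for a change of at least 2-fold. No replicate block was used in the main fits, since the replicate numbers were no established pairing. Still, 11 of 12 A549 arrays and 10 of 12 Calu-6 arrays lay closest to their own number, and a block was tried as an alternative. The labels call the replicates biological without saying whether they were separate cultures, which the p values assume.

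Genes were named by a rule written in advance. It took the 10 highest and 10 lowest changes at 0.003 puffs/ml in each line among named, called genes whose treated and untreated arrays did not overlap, and the 3 highest and 3 lowest at the other doses and for the slope. It took the 6 highest and 6 lowest for the difference between lines and the 8 highest and 8 lowest for the untreated lines. DKK1 was named throughout, and of the 25 gene lists also fixed in advance up to 4 members with the smallest p. CYP1A1, CYP1B1, NQO1, HMOX1, EZH2, SUZ12 and BMI1 were also to be named at 0.003 puffs/ml, of which the deposited lists named the first pair. A named member was found for 12 lists, and the other 13 were not examined. Set tests were not run on these lists, because their named members had been selected by the authors on the same arrays. A further 23 genes, those added in the closing section and VIPR1, LBH and PLAC8, were named after their values were seen. ACSL5 and PRICKLE1 fell under the rule for the slope. Some genes under the rule and in the lists are not printed.

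The tests were tried on simulated data with 200 of 54613 probe sets changed. Normal noise was drawn independently for each probe set and array, with the spread of that probe set within groups. It held no correlation between probe sets, no replicate effect and no outlying array, so recovery on the real arrays may differ. False calls numbered 2 at 0.003 puffs/ml in A549, 6 in Calu-6 and 9 in the difference between lines. A log2 change of 1 was recovered for 61.2% of probe sets at 0.003 puffs/ml in A549, 68.7% in Calu-6 and 40.3% in the difference between lines. A log2 change of 2 was recovered for 95.5%, 100% and 93.9%, and a log2 change of 0.5 for 16.4%, 16.4% and 2.99%. Alternatives were subtraction of array medians, quantile normalization, a replicate block, array weights, robust eBayes, ACTB 3′ minus 5′ signal as a covariate, all 24 or only 6 arrays in the fit, a slope on the rank of the dose, fold limits, leaving out each array in turn, and keeping the Calu-6 array farthest from its group out of the spread. An arm left with 2 arrays shared the spread of the other groups. Gene sets across lines were tested with camera, with a preset correlation of 0.01 or an estimated one, and with fry. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.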

Results

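RNA was measured on 24 Affymetrix HG-U133 Plus 2 arrays from A549 and Calu-6 cells, established human lung cancer lines. Each line was left untreated or exposed to tobacco smoke condensate (TSC), the collected particulate matter of cigarette smoke, at 0.0005, 0.001 or 0.003 puffs/ml. Each of the 8 groups had 3 arrays, whose titles call them biological replicates, and this number limits the precision. The table held log2 values relative to each probe set's median over the 24 arrays, so changes are given and levels are not. Log2 changes are followed by the standard error of the fit, and each compares 3 treated with 3 untreated arrays unless stated. A probe set was called when its Benjamini-Hochberg adjusted p was under 0.05 over the 54613 probe sets tested. Gene names came from the authors' lists of regulated probe sets, so 306 probe sets carried 1 name, and counts refer to probe sets. The lists were chosen on these arrays, so no gene group described here is independent evidence of its direction.

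The title of the study concerns repression of DKK1, a secreted antagonist of Wnt signalling. DKK1 fell in A549 at every dose, by 2.00-fold at 0.0005, 2.22-fold at 0.001 and 2.38-fold at 0.003 puffs/ml. The log2 changes were -0.997, -1.15 and -1.25, each ± 0.12, with adjusted p of 0.00207, 0.000550 and 0.000245. In Calu-6, DKK1 fell at 0.001 puffs/ml (-1.88 ± 0.25, 3.69-fold, adjusted p = 0.0119) and at 0.003 puffs/ml (-1.89 ± 0.25, 3.70-fold, adjusted p = 0.00550). At 0.0005 puffs/ml its change in Calu-6 was -1.58 ± 0.25 with an adjusted p of 0.0712, which did not pass. Over 15 alternatives that adjusted p ranged from 0.000350 to 0.448 and passed in 5. These included array weights (0.000350), all 24 arrays in 1 fit (0.00100) and a replicate block (0.0302). The others were the fit without control replicate 2 (0.0429) and the fit without TSC 0.001 replicate 1 (0.0241). In both lines every treated array lay under every untreated array. The change at 0.003 puffs/ml differed between the lines by 0.63 ± 0.29, A549 minus Calu-6, with an adjusted p of 0.581. No slope of DKK1 in proportion to dose passed, with adjusted p of 0.786 in A549 and 0.582 in Calu-6, while a slope on the rank of the dose passed in both lines (0.0371 and 0.0484, the lowest of 19 alternatives in each line, whose highest were 1.00). Untreated cells of the lines differed by -0.22 (adjusted p = 0.534). In a fit of the 6 arrays compared, the A549 value at 0.0005 puffs/ml had an adjusted p of 0.0573, within a range of 0.000194 to 0.0573 over 14 alternatives. The Calu-6 call at 0.001 puffs/ml was lost without control replicate 1 (adjusted p = 0.0719), control replicate 3 (0.0829) or TSC 0.001 replicate 2 (0.0752) and with only 6 arrays (0.245), within a range of 1.75e-05 to 0.245.

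**Figure D1:**
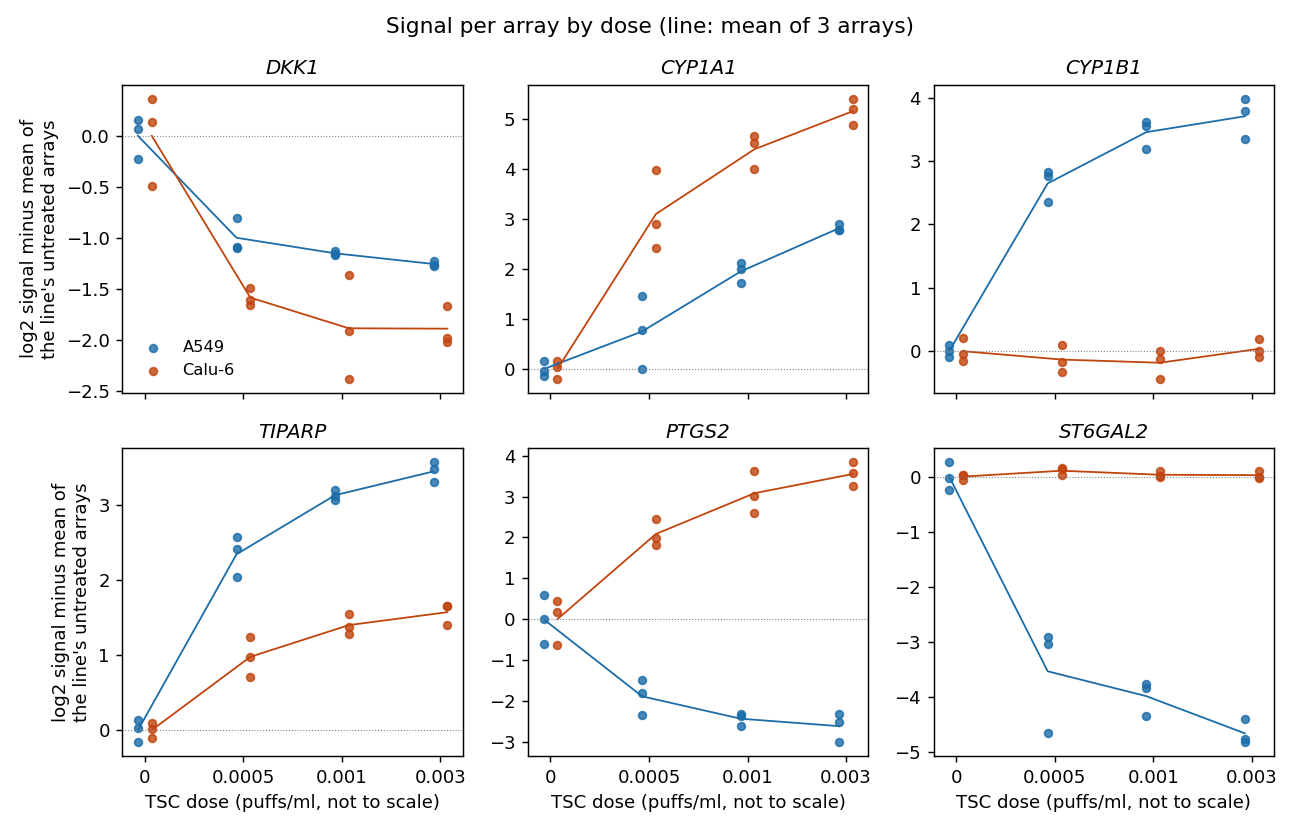
Log2 signal of 6 genes on each array, minus the mean of the 3 untreated arrays of the same line, against TSC dose in puffs/ml (doses evenly spaced, not to scale); points are arrays and lines join the means of 3 arrays. DKK1 reached -1.25 in A549 and -1.89 in Calu-6 at 0.003 puffs/ml, CYP1B1 reached 3.71 in A549 against 0.04 in Calu-6, and PTGS2 reached -2.62 in A549 against 3.55 in Calu-6.

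The highest dose in A549 asked which genes respond to TSC in this line. Genes that the aryl hydrocarbon receptor, a sensor of polycyclic aromatic compounds, is known to induce were among the largest rises. CYP1B1, a cytochrome P450 that oxidises aromatic hydrocarbons, rose 13.1-fold (log2 3.71 ± 0.18), and its other probe sets rose by 3.53 and 3.48. TIPARP, an ADP-ribosyltransferase that dampens this receptor, rose 10.9-fold (3.44 ± 0.14), and CYP1A1, the classic receptor target, rose 7.04-fold (2.82 ± 0.27). ST6GAL2, a sialyltransferase, fell 25.4-fold (-4.67 ± 0.36), and OR51E2, an olfactory receptor, fell 16.1-fold (-4.01 ± 0.22). In all, 399 probe sets were called at 0.003 puffs/ml in A549, 118 higher and 281 lower (70.4% lower), of which 212 changed at least 2-fold.

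Other large falls in A549 were C6orf176, now named LINC00473, a long non-coding RNA (-3.94 ± 0.26), and DEFB1, an antimicrobial beta-defensin (-3.13 ± 0.24). RBP4, the carrier of retinol in plasma, fell by 3.10 on the log2 scale (± 0.32), and NNMT, which methylates nicotinamide, fell by 2.86 (± 0.17). NEB, which encodes the muscle protein nebulin, fell by 2.80 (± 0.35), and OR51E1, another olfactory receptor, fell by 2.61 (± 0.17). PTGS2, the inducible cyclooxygenase of prostaglandin synthesis, fell 6.13-fold (-2.62 ± 0.29). GCH1, the first enzyme of tetrahydrobiopterin synthesis, fell 6.06-fold (-2.60 ± 0.20). Among the rises was EREG, a ligand of the epidermal growth factor receptor (1.99 ± 0.35). PCDH9, a protocadherin, rose by 1.79 ± 0.27, C20orf114, now BPIFB1, a secreted airway protein, by 1.71 ± 0.25, and ABCA1, a cholesterol exporter, by 1.61 ± 0.24.

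Of 11 genes listed as aryl hydrocarbon receptor targets, 6 were named. In A549 at 0.003 puffs/ml 5 rose, including ALDH1A3, a retinaldehyde dehydrogenase (1.81 ± 0.21), and AHRR, the repressor of the receptor (1.80 ± 0.21). NEDD9, an adhesion adaptor protein, fell on both probe sets (-1.31 ± 0.21 and -1.16 ± 0.22). The counts were 7 probe sets up and 2 down over all probe sets and also adjusted over the list alone. Adjustment over a list alone covered only its named members, which the authors had selected on these arrays. Passing it therefore adds no support. Among Wnt/beta-catenin targets SOX9, a transcription factor, fell (-2.41 ± 0.25 and -1.98 ± 0.15), CD44, a hyaluronan receptor, fell on 4 of 5 probe sets (-1.12 to -1.33), and MMP7, a matrix metalloproteinase, rose (1.5 ± 0.13). Adjusted over the list alone, 7 probe sets of these targets fell and 1 rose. DKK1 was the named Wnt antagonist, lower also when adjusted over the list alone, which for 1 probe set is the unadjusted p.

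The remaining lists in A549 at 0.003 puffs/ml held 1 to 4 named genes each. Among immediate early genes and MAPK feedback, DUSP5 and DUSP6, phosphatases that switch off MAP kinases, fell (-1.34 ± 0.17, and -0.90 ± 0.14 on 1 of 3 probe sets), while EREG and PHLDA1, a growth-factor-inducible protein, rose (PHLDA1 by 1.31 and 1.14 on 2 of 3 probe sets). Adjusted over the list alone, 4 of its probe sets rose and 4 fell. Both named airway markers, the mucins MUC5B (-2.09 ± 0.29) and MUC5AC (-1.35 ± 0.22), fell, as 2 did when adjusted over the list alone. Among stress genes TP53INP1, a p53 target, rose (1.59 ± 0.15), NUPR1, a stress-induced chromatin protein, rose (1.56 ± 0.14), and VLDLR, a lipoprotein receptor, fell (-1.10 ± 0.18). CDKN1A, a cell cycle inhibitor induced by p53, was at 0.56 ± 0.12 (adjusted p = 0.0568) and TRIB3, a pseudokinase, at -1.07 ± 0.28 (adjusted p = 0.142). Adjusted over the list alone, 2 p53 targets rose, and 1 ATF4 gene rose and 2 fell. Of the interferon-stimulated genes OAS1, an RNA sensor, fell (-1.35 ± 0.15), also when adjusted over the list alone. NFKBIZ, an NF-kB cofactor, was at 1.26 ± 0.26 (adjusted p = 0.0526). The inflammatory list had PTGS2 down on 2 probe sets, and 1 up and 2 down adjusted over the list alone.

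Of the hypoxia genes in A549, ADM, a vasodilator peptide (1.09 ± 0.17), and PFKFB3, a regulator of glycolysis (1.10 ± 0.19), rose, and 3 rose adjusted over the list alone. Of the mesenchymal genes FN1, fibronectin, fell (-1.05 ± 0.14), also when adjusted over the list alone. LYZ, lysozyme, the 1 named leukocyte marker, was at 0.70 ± 0.25 (adjusted p = 0.355). With 1 probe set in its list, it passed adjusted over the list alone on its unadjusted p in the limma fit (0.0155). Of these arrays, A549 TSC 0.003 replicate 3 had the highest 3′ minus 5′ ACTB signal of its line, 0.74, and without it 300 probe sets were called. The count was 206 with only the 6 arrays compared, 250 without control replicate 1, 200 without control replicate 3 and 213 without TSC 0.003 replicate 2, and quantile normalization brought the share of falls from 70.4% to 52.4%. Without 1 array the calls of EREG (adjusted p up to 0.0775, without TSC 0.003 replicate 3), NEDD9 (0.140, without control replicate 3), PHLDA1 (0.0892, without TSC 0.003 replicate 3), VLDLR (0.0769), PFKFB3 (0.0823) and MUC5AC (0.0526; these 3 without TSC 0.003 replicate 2) and of 2 CD44 probe sets (0.0636, without control replicate 3) were lost.

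At the lower doses in A549 the same leading genes moved. CYP1B1 rose by 2.86 ± 0.13 at 0.0005 puffs/ml and by 3.46 ± 0.18 at 0.001 puffs/ml. TIPARP rose by 2.34 ± 0.14 and 3.13 ± 0.14, and MGAM, an enzyme of starch digestion, by 1.92 and 2.69. CYP1A1 was at 0.75 ± 0.27 at 0.0005 puffs/ml (adjusted p = 0.441) and rose by 1.95 ± 0.27 at 0.001 puffs/ml. ST6GAL2 fell, with log2 changes of -3.54 at 0.0005 and -3.99 at 0.001 puffs/ml, and so did OR51E2, with -3.29 and -3.68. DEFB1 changed by -2.85 at 0.0005 puffs/ml and C6orf176 by -3.38 at 0.001 puffs/ml. In all, 249 probe sets were called at 0.0005 puffs/ml (61 higher, 188 lower) and 340 at 0.001 puffs/ml (152 higher, 188 lower). No probe set had a slope in proportion to dose in the limma fit, with 3050 at an unadjusted p under 0.05, and a slope on the rank of the dose called 90. Leaving out single arrays gave 112 to 212 calls at 0.0005 puffs/ml, the lowest without control replicate 3, and 172 to 248 at 0.001 puffs/ml, again the lowest without control replicate 3. After quantile normalization falls made up 57.7% in place of 75.5% of the calls at 0.0005 puffs/ml, and 43.3% in place of 55.3% at 0.001 puffs/ml, where rises then outnumbered falls.

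In Calu-6 at 0.003 puffs/ml the largest rise among named genes was that of CYP1A1, 35.6-fold (5.15 ± 0.32). PTGS2 rose 11.7-fold (3.55 ± 0.31), and GBP3, an interferon-inducible GTPase, rose 9.11-fold (3.19 ± 0.29). PSMB9, a subunit of the immunoproteasome, rose 6.05-fold (2.60 ± 0.18), and AKAP12, a scaffold of protein kinase A, rose 4.52-fold (2.18 ± 0.19). Of the 83 called falls 7 carried a name, and these were smaller than the leading rises. After DKK1, NEDD9 fell by 1.33 on the log2 scale (± 0.26) and PLXNA2, a semaphorin receptor, fell by 1.26 (± 0.18). In all, 322 probe sets were called, 239 higher and 83 lower (25.8% lower), of which 193 changed at least 2-fold and 42 carried a name.

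Further rises in Calu-6 were NMI, an interferon-induced protein (2.03 ± 0.22), and RARRES3, now PLAAT4, a retinoid-inducible phospholipase (1.93 ± 0.32). GCH1 rose by 1.84 ± 0.32 and CDKN1A by 1.81 ± 0.25. PRICKLE1, a planar cell polarity protein, fell by 1.16 (± 0.16), and NR3C2, the mineralocorticoid receptor, fell by 1.16 (± 0.17). C9orf58, now AIF1L, fell by 1.12 (± 0.19), and ACOX2, a peroxisomal oxidase of branched fatty acids, fell by 0.70 (± 0.13).

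Among the aryl hydrocarbon receptor targets in Calu-6, 4 of 6 named genes rose, CYP1A1, ALDH1A3 (2.37 ± 0.33), AHRR (1.69 ± 0.19) and TIPARP (1.57 ± 0.14), and NEDD9 fell on 1 of 2 probe sets. CYP1B1 was at 0.26, 0.04 and -0.01 on its 3 probe sets, with adjusted p of 0.919, 0.974 and 0.988. Adjusted over the list alone, 4 probe sets rose and 2 fell. Of the Wnt/beta-catenin targets CD44 rose on 4 of 5 probe sets (1.07 to 1.23), with 5 up and 1 down adjusted over the list alone, and SOX9 was at -0.71 ± 0.26 (adjusted p = 0.594). Of the hypoxia genes ADM (0.91 ± 0.13) and SLC2A1, a glucose transporter (1.26 ± 0.15), rose, and 3 rose adjusted over the list alone. PTGS2 was the inflammatory gene that rose, on 2 probe sets, also adjusted over the list alone. Of the p53 targets CDKN1A rose and TP53INP1 was at -0.63 ± 0.27 (adjusted p = 0.753), with 1 up and 1 down adjusted over the list alone. DKK1, as Wnt antagonist, fell also when adjusted over the list alone, which for 1 probe set is the unadjusted p.

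The other lists in Calu-6 at 0.003 puffs/ml had no call over all probe sets. Among the interferon-stimulated genes OAS1 was at 0.03 (adjusted p = 0.987) and did not pass adjusted over the list alone. FN1, of the mesenchymal genes, was at -0.49 (adjusted p = 0.80) and lower when adjusted over the list alone. LYZ, at -0.92 (adjusted p = 0.181), was lower adjusted over the list alone, which for 1 probe set is the unadjusted p. It passed over all probe sets (0.0151) without TSC 0.001 replicate 1 in the spread. The ATF4, MAPK and airway lists had 0 calls adjusted over the list alone. Calu-6 TSC 0.003 replicate 2 had the highest 3′ minus 5′ ACTB signal of all arrays, 1.19, and without it 200 probe sets were called. TSC 0.001 replicate 1, which deviated most from its group of all arrays (0.356), enters the spread of these tests, and without it 566 were called. The count was 168 without control replicate 1, 123 without control replicate 3, 174 without TSC 0.003 replicate 1 and 125 without TSC 0.003 replicate 3. Without 1 array the calls of NEDD9 (adjusted p up to 0.233), NR3C2 (0.0632), PLXNA2 (0.0540), ADM (0.0501; these 4 without control replicate 3), GCH1 (0.135), RARRES3 (0.121), C9orf58 (0.135), ACOX2 (0.220), ALDH1A3 (0.050; these 5 without TSC 0.003 replicate 3) and of all 4 called CD44 probe sets (0.188, without control replicate 3) were lost.

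At the lower doses Calu-6 had few calls, led again by CYP1A1. It rose 8.55-fold at 0.0005 puffs/ml (3.10 ± 0.32, adjusted p = 0.0213) and 21.0-fold at 0.001 puffs/ml (4.39 ± 0.32). PTGS2 rose on 1 probe set by 1.89 ± 0.25 at 0.0005 puffs/ml (adjusted p = 0.0434) and by 3.08 ± 0.31 at 0.001 puffs/ml on its other probe set. PSMB9 rose by 1.82 at 0.0005 puffs/ml (adjusted p = 0.0213), and GBP3 by 2.50 at 0.001 puffs/ml. C9orf58 fell by 1.23 on the log2 scale and NR3C2 fell by 1.01 at 0.001 puffs/ml. There were 12 called probe sets at 0.0005 puffs/ml (10 higher, 2 lower, and 56 without TSC 0.001 replicate 1 in the spread) and 124 at 0.001 puffs/ml (84 higher, 40 lower). Both counts were higher with a replicate block. A slope in proportion to dose was called for 13 probe sets (11 rising, 2 falling), among them ACSL5, a long-chain acyl-CoA synthetase (0.45 ± 0.06 per 0.001 puffs/ml), and PRICKLE1 (-0.36 ± 0.05), both with an adjusted p of 0.0390. Leaving out single arrays gave 0 to 23 calls at 0.0005 puffs/ml (0 without control replicate 1), 16 to 203 at 0.001 puffs/ml (16 without control replicate 3, 203 without TSC 0.001 replicate 1) and 0 to 30 for the slope (0 without TSC 0.003 replicate 1). Without 1 array the adjusted p reached 0.151 for CYP1A1 and PSMB9 (without control replicate 1) and 0.333 for PTGS2 (without control replicate 3) at 0.0005 puffs/ml, 0.0511 for GBP3, 0.206 for NR3C2 (both without control replicate 3) and 0.131 for C9orf58 (without control replicate 1) at 0.001 puffs/ml, and 0.224 for the slope of ACSL5 and 0.20 for that of PRICKLE1 (both without TSC 0.003 replicate 2).

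The difference between the responses of the lines at 0.003 puffs/ml was tested in a fit of all 24 arrays. PTGS2 fell in A549 and rose in Calu-6, a difference of -6.17 ± 0.45 (A549 minus Calu-6, log2), the largest of the named genes. GCH1 differed by -4.44 ± 0.40, and PLA2G4A, the phospholipase that releases arachidonic acid for prostaglandin synthesis, by -3.56 ± 0.24, with -2.08 in A549 against 1.48 in Calu-6. ST6GAL2 (-4.69 ± 0.40), C6orf176 (-3.96 ± 0.31) and OR51E2 (-3.85 ± 0.27) fell in A549 while Calu-6 had no call, but untreated Calu-6 lay 5.35, 4.81 and 4.91 log2 units under untreated A549, where a fall was not shown to be measurable. In the other direction were CYP1B1 (3.67 ± 0.25), TP53INP1 (2.21 ± 0.32), TIPARP (1.87 ± 0.20), MMP7 (1.85 ± 0.21), NUPR1 (1.81 ± 0.30) and C20orf70, now BPIFA2 (1.77 ± 0.36). CYP1A1 rose more in Calu-6 (difference -2.34, adjusted p = 0.0104), whereas the differences of AHRR (0.11, adjusted p = 0.947) and ALDH1A3 (-0.56, adjusted p = 0.790) did not pass. The test called 443 probe sets, 99 with the higher change in A549 and 344 with the lower, and 292 without A549 TSC 0.003 replicate 2. C20orf70 had an adjusted p of 0.0603 without Calu-6 control replicate 1, and quantile normalization brought the share with the lower change in A549 from 77.7% to 66.3%.

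Of the probe sets called at 0.003 puffs/ml, 27 were called in both lines, where 2.35 were expected from the sizes of the calls (two-sided Fisher's exact test across probe sets, p = 1.88e-20; probe sets are not independent). Of these, 12 rose in both lines, including CYP1A1, TIPARP, AHRR, ALDH1A3, ADM, VIPR1, a receptor of vasoactive intestinal peptide (1.05 in A549 and 1.65 in Calu-6), LBH (1.22 and 1.72) and PLAC8 (1.12 and 0.77). DKK1, NEDD9 and ACOX2 were among the 5 that fell in both. The other 10, where 1.23 were expected, fell in A549 and rose in Calu-6. They held GCH1, PLA2G4A and repeated probe sets of PTGS2 and CD44. No probe set rose in A549 and fell in Calu-6, where 0.18 were expected. Across all 54613 probe sets the changes in the lines had a Pearson correlation of 0.0167, and across the 694 called in either line 0.206. The overlap was 15 with only the 6 arrays compared, 17 without A549 control replicate 3 or without Calu-6 TSC 0.003 replicate 1, 14 without Calu-6 control replicate 3 and 13 without Calu-6 TSC 0.003 replicate 3. Without 1 array the Calu-6 calls of LBH (adjusted p up to 0.186, without TSC 0.003 replicate 3) and PLAC8 (0.238, without control replicate 1) and the A549 call of VIPR1 (0.0595, without control replicate 3) were lost.

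**Figure D2:**
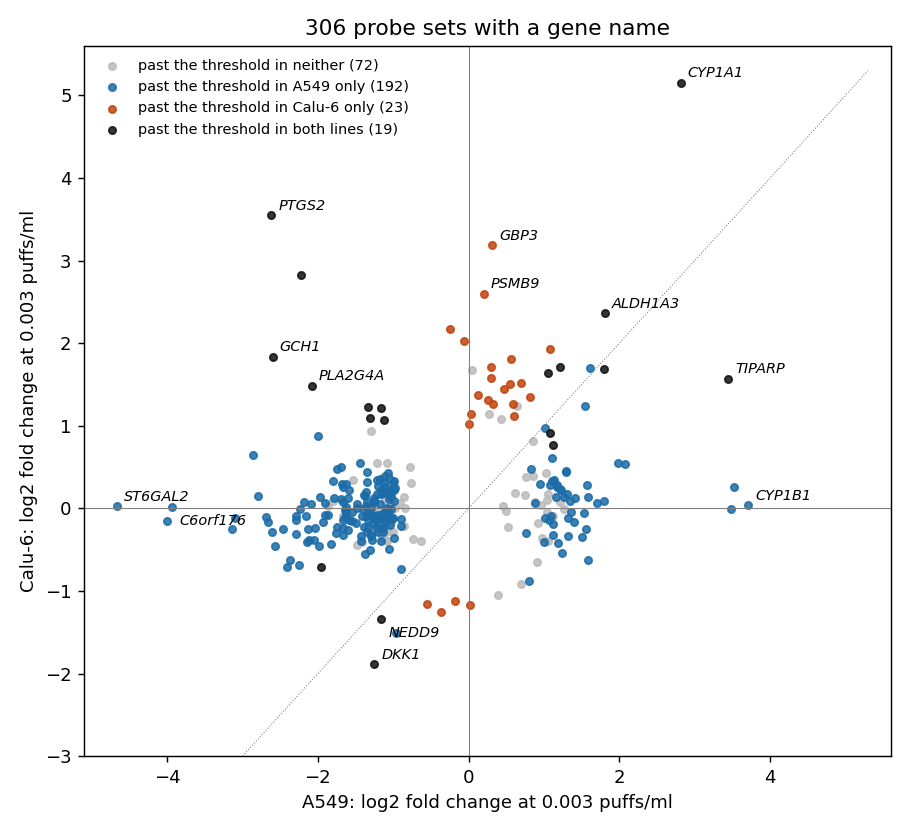
Log2 fold change at 0.003 puffs/ml in Calu-6 against that in A549, 1 point for each of the 306 probe sets with a gene name, coloured by the lines in which its adjusted p was under 0.05; the dotted line marks equal change. The threshold was passed in both lines by 19 probe sets, in A549 only by 192, in Calu-6 only by 23 and in neither by 72. The names come from the authors' lists, of 309 probe sets in A549 and 34 in Calu-6. These counts therefore do not compare the breadth of the responses. Over all 54613 probe sets, 399 were called in A549 and 322 in Calu-6, with 27 called in both.

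Untreated cells gave the background of these responses. Higher in A549 were NTS, the precursor of neurotensin (8.01 ± 0.16, 258-fold), FGB, the fibrinogen beta chain (7.92 ± 0.21), and TM4SF20, a membrane protein (6.82 ± 0.15). INSL4, a placental insulin-like peptide (6.70 ± 0.18), KYNU, an enzyme of tryptophan breakdown (6.66 ± 0.17), CD24, a surface glycoprotein (6.58 ± 0.21), NNMT (6.43 ± 0.18) and PAQR5, a progesterone-binding membrane receptor (5.43 ± 0.13), were also higher in A549. Higher in Calu-6 were NAV3, a microtubule-associated protein (-4.67 ± 0.21, A549 minus Calu-6), PHLDA1 (-4.10 ± 0.21), LFNG, a glycosyltransferase that modifies Notch (-4.02 ± 0.28), and DUSP6 (-3.15 ± 0.18). CHGB, a protein of secretory granules (-2.87 ± 0.22), PLAC8 (-2.81 ± 0.15), AHRR (-2.55 ± 0.21) and SNAP25, a protein of synaptic vesicle fusion (-2.41 ± 0.17), were higher in Calu-6 as well. At an adjusted p under 0.05 and at least 2-fold, 5388 probe sets differed, 3175 higher in A549 and 2213 higher in Calu-6, and without the fold limit 13266 did. Named genes cannot stand for all differences, since the names came from lists of TSC-regulated probe sets.

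The authors' lists were set beside the fits as a description of their overlap. The A549 list held 309 probe sets, 91 up and 218 down at 0.003 puffs/ml, of which 307 were tested and 225 were called here (62 up, 163 down). The Calu-6 list held 34, 28 up and 6 down, of which 29 were called (24 up, 5 down). Every listed probe set had the listed direction. In both lists were 5 probe sets, those of ALDH1A3, RARRES3, DKK1, CYP1A1 and TIPARP. Applying the stated criteria, an unadjusted p of at most 0.05 over the conditions of a line and a 2-fold change, to the deposited values gave the same 309 probe sets in A549 but 279 in Calu-6, of which 34 were those listed. RARRES3 in A549 was at 1.08 ± 0.24 at 0.003 puffs/ml, with an adjusted p of 0.0708 that did not pass.

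The control probe sets for ACTB and GAPDH gave 1 measure of RNA quality per array. The 3′ minus 5′ signal of ACTB, relative to all arrays, reached 0.07 in untreated A549 and 0.24 in untreated Calu-6. It was 0.27 in A549 TSC 0.0005 replicate 2, 0.50 in A549 TSC 0.001 replicate 1, 0.74 in A549 TSC 0.003 replicate 3 and 1.19 in Calu-6 TSC 0.003 replicate 2. GAPDH was at 0.20, 0.28 and 0.40 in the last 3 of these.

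**Figure D3:**
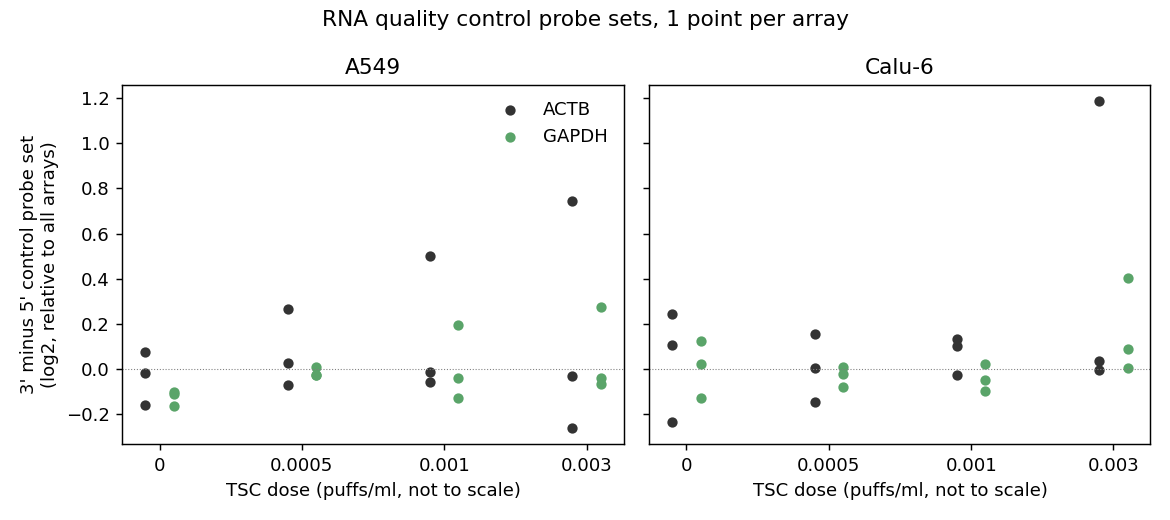
3′ minus 5′ signal (log2, relative to all arrays) of the ACTB and GAPDH control probe sets against TSC dose in puffs/ml, with A549 on the left and Calu-6 on the right and 1 point per array. The 3 highest ACTB values, 0.50, 0.74 and 1.19, were on treated arrays.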

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

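The tests of technical explanations in this part were set out before their results were seen, while the counts with Calu-6 TSC 0.001 replicate 1 kept out of the spread and the tests of degraded RNA were chosen afterwards, the latter in place of a ratio of fold changes that the choice of called probe sets nearly fixes. Groups of 3 arrays are too small for the test of single outlying arrays that larger groups would get.

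Calu-6 TSC 0.001 replicate 1 stood apart in other measures. Its differences from replicates 2 and 3 had SDs of 0.529 and 0.568 over all probe sets, against 0.258 between those, and its deviation from the group mean, 0.356, was the highest of all arrays. On the first component of the Calu-6 arrays, with 44.5% of the variance, it scored 0.69 and control replicate 1 scored 0.43, with the rest from -0.31 to 0.12. Without it the count at 0.001 puffs/ml went from 124 to 203, and with it kept out of the spread the counts at 0.0005 and 0.003 puffs/ml went from 12 to 56 and from 322 to 566, the 566 holding all 322.

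At 0.003 puffs/ml the responses of the lines differed in the test of the difference itself (log2, A549 minus Calu-6) for many of the named genes, those with the lower change in A549 first. The differences were -5.06 for PTGS2 on its less changed probe set, -4.69 for ST6GAL2, -4.44 for GCH1, -3.96 for C6orf176, -3.85 for OR51E2, -3.56 for PLA2G4A, -3.51 for NNMT, -2.99 for RBP4, -2.95 for NEB, -2.88 for DEFB1, -2.87 for GBP3 and PDK4, -2.56 for CD44, -2.42 for AKAP12, -2.40 for PSMB9, -2.34 for CYP1A1 and -2.32 for OR51E1. They were -2.20 for VEGFC, -2.14 for MUC5B, -2.11 for TFF1, -2.08 for NMI, -2.07 for INSL4, -1.99 for IGFBP3, -1.87 for NTS, -1.79 for DUSP5, -1.75 for SGK1, -1.57 for VCAN, -1.54 for SOX9, -1.49 for VLDLR, -1.43 for NOTCH3, -1.42 for UBE2L6 and -1.40 for JAG1. Smaller ones were -1.39 for NR4A2, -1.38 for OAS1, -1.33 for NR4A1, -1.28 for TLR3, -1.25 for ACOX2, -1.24 for CDKN1A, -1.02 for APOL2 and -0.95 for PARP14. With the higher change in A549 were CYP1B1 (3.50 on the probe set with the smallest p), TP53INP1 (2.21), TIPARP (1.87), MMP7 (1.85), NUPR1 (1.81), C20orf70 (1.77), PCDH9 (1.70), C20orf114 (1.64), LYZ (1.62) and PRICKLE1 (1.19). Of the 25 genes with the lower change in A549 and no call in Calu-6, 18 were over 2 log2 units lower in untreated Calu-6 than in untreated A549, by 8.01 for NTS, 6.70 for INSL4, 6.43 for NNMT, 5.35 for ST6GAL2, 4.91 for OR51E2 and 4.81 for C6orf176. Signal over background could not be assessed, so a fall of these genes in Calu-6 was not shown to be measurable, and the differences do not show that Calu-6 failed to respond. Without A549 TSC 0.003 replicate 2 the adjusted p was 0.156 for PARP14, 0.124 for TLR3, 0.119 for CDKN1A, 0.102 for VCAN and 0.0781 for APOL2. It was 0.0899 for PCDH9 without A549 TSC 0.003 replicate 3, 0.0656 for C20orf114 without Calu-6 control replicate 3 and 0.0603 for C20orf70 without Calu-6 control replicate 1.

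In the control probe sets the 3′ minus 5′ signal of ACTB lay above that of every untreated array of the same line in A549 TSC 0.0005 replicate 2 (0.27), A549 TSC 0.001 replicate 1 (0.50), A549 TSC 0.003 replicate 3 (0.74) and Calu-6 TSC 0.003 replicate 2 (1.19). The untreated maxima were 0.07 in A549 and 0.24 in Calu-6.

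Of the 399 calls in A549 at 0.003 puffs/ml, 264 (66.2%) stood without TSC 0.003 replicate 3, the array with signs of degraded RNA, and cannot come from it, while 135 ended. The loss of any 1 of the other arrays compared ended 120 to 203 calls, so for the 135 degraded RNA and the smaller group cannot be told apart. RNA of Calu-6 in the treated samples would raise the 200 probe sets highest in untreated Calu-6 against A549, but their median change was 0.0885 with quartiles of -0.126 and 0.227. Subtraction of array medians left the share of falls at 73.3%, while quantile normalization brought it to 52.4%. Quantile normalization forces the same distribution on every array. On values centred per probe set it can also even out a real excess of falls. It therefore cannot decide whether that excess came from array scaling. A response of the cells to TSC therefore remains as a hypothesis for the 264, while the 135 and the balance of direction stay open.

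The 322 calls in Calu-6 at 0.003 puffs/ml were weighed in the same way. Without TSC 0.003 replicate 2, 176 (54.7%) kept their call and 146 lost it, against 117 to 199 without any 1 of the other arrays compared, so degraded RNA stays open for the 146. The 200 probe sets highest in untreated A549 had a median change of -0.0142, with quartiles of -0.161 and 0.140, which argues against RNA of A549. The excess of rises was not removed by scaling, since falls made up 29.9% of calls in the rescaling nearest to an even share. A response of these cells to TSC may thus underlie the 176, as a hypothesis found and tested on the same arrays.

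Other splits of the arrays were counted for each fitted comparison. In A549 the real split was the 1 of 10 with the most calls at each dose, with 249, 340 and 399 calls against at most 0 in the others, and 10 splits are too few for a share under 0.05. The same holds in Calu-6 at 0.0005 puffs/ml (12 calls, 1 of 10, others at most 0) and 0.003 puffs/ml (322 calls, 1 of 10, others at most 0) and for the untreated lines (5388 calls, 1 of 10, others at most 0). In Calu-6 at 0.001 puffs/ml 2 of 10 splits gave at least the 124 real calls. The other, with TSC 0.001 replicate 1 and control replicates 1 and 3 set against the remaining 3 arrays, gave 6783, which points to a structure of these samples. For the slope in A549 the real count of 0 makes all regroupings (100 of 100, the highest 660) reach it by construction, so this says nothing about chance, and limma had 3050 probe sets at an unadjusted p under 0.05. For the slope in Calu-6, 2 of 100 gave as many as the 13 real calls, the highest other 114, and for the difference between lines 1 of 100 did, with 443 real calls against at most 218. These shares are under 0.05, but the regroupings ignored the replicate number. They also mixed treated and untreated arrays within groups, which adds treatment differences to the spread and lowers their counts. The shares therefore do not exclude chance. The 13 slope calls also fell to 0 with the ACTB covariate and without TSC 0.003 replicate 1 or 2.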

How the results depend on the processing

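The alternatives were fixed before the data were examined, except robust eBayes, the ACTB covariate, Calu-6 TSC 0.001 replicate 1 kept out of the spread and the recomputed list criteria, which were chosen afterwards. Of 287 values of named genes followed, 185 were past the threshold. No value called in the main fit or in the alternative changed sign between them, which fits of largely the same arrays make likely. Values called in neither fit did change sign, 33 times when leaving out 1 array and 12 times with array weights. The ACTB covariate gave 8 such changes, quantile normalization 6 and subtraction of array medians 3. Of the 185, 139 kept their call without each array in turn and 46 lost it at least once (13 of 66 at 0.003 puffs/ml in A549 and 16 of 34 in Calu-6).

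Array weights raised the counts most, to 813, 1051 and 2638 in A549 at 0.0005, 0.001 and 0.003 puffs/ml, 1300, 9194 and 4146 in Calu-6, 483 for the Calu-6 slope, 8276 for the difference between lines and 386 for the overlap. With all 24 arrays in 1 fit there were 399 calls in A549 at 0.0005 puffs/ml, 113, 274 and 585 in Calu-6 and an overlap of 50. With only the 6 arrays compared there were 114 in A549 at 0.0005 and 206 at 0.003 puffs/ml, 1 in Calu-6 at 0.0005 and 1 at 0.001 puffs/ml and an overlap of 15, with fewer arrays behind each spread. A 2-fold limit left 132, 182 and 212 in A549 and 77 and 193 in Calu-6 at 0.001 and 0.003 puffs/ml by its construction, and dropping it for the untreated lines gave 13266.

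Replicate numbers were no established pairing, but 11 of 12 A549 arrays and 10 of 12 Calu-6 arrays lay closest to their own number. Correlations between arrays of the same number, after removal of group means, had a median of 0.15 in A549, 12 of 18 over 0.1, and 0.31 in Calu-6, 15 of 18 over 0.1. As a hint, a replicate block gave 62, 259 and 603 calls in Calu-6, 71 for its slope, 691 for the difference between lines and an overlap of 55, and DKK1 at 0.0005 puffs/ml in Calu-6 then had an adjusted p of 0.0302 (range over its 15 alternatives 0.000350 to 0.448). The ACTB covariate gave 30 calls in Calu-6 at 0.0005 puffs/ml and 0 for its slope, and subtraction of array medians 3 for that slope. A slope on the rank of the dose called 90 probe sets in A549 and 326 in Calu-6, and DKK1 then passed in both lines (adjusted p of 0.0371 and 0.0484, ranges to 1.00). With Calu-6 TSC 0.001 replicate 1 kept out of the spread there were 56 and 566 calls in Calu-6 at 0.0005 and 0.003 puffs/ml. Where the cause is not named, the cause was not tested.

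Leaving out single arrays in A549 gave 112 to 212 calls at 0.0005 puffs/ml (112 without control replicate 3, 143 without control replicate 1, 147 without TSC 0.0005 replicate 2, 151 without replicate 3). At 0.001 puffs/ml it gave 172 to 248 (172 without control replicate 3, and 183, 176 and 197 without TSC 0.001 replicates 1, 2 and 3), at 0.003 puffs/ml 200 to 337 and for the slope 0 to 0. In Calu-6 it gave 0 to 23 at 0.0005 puffs/ml (0 without control replicate 1, control replicate 3 or TSC replicate 3, 1 and 3 without TSC replicates 1 and 2, 23 without control replicate 2). At 0.001 puffs/ml it gave 16 to 203 (28 and 16 without control replicates 1 and 3, 203, 23 and 77 without TSC replicates 1, 2 and 3). At 0.003 puffs/ml it gave 123 to 229 (168 and 123 without control replicates 1 and 3, and 174, 200 and 125 without TSC replicates 1, 2 and 3). For the Calu-6 slope it gave 0 to 30: 0 without TSC 0.003 replicate 1 or 2, 30 without TSC 0.0005 replicate 1, and 1 without any control, TSC 0.0005 replicate 2 or 3 or TSC 0.003 replicate 3. The ranges were 292 to 423 for the difference between lines, 5358 to 5518 for the untreated lines, 13 to 29 for the overlap, and 159 to 203 and 21 to 29 for listed probe sets called in A549 and Calu-6. Where limma counted 0 calls, 2213 to 6800 probe sets in the A549 slope, 1147 to 1377 at 0.0005 puffs/ml in Calu-6 and 2241 to 4310 in the Calu-6 slope had an unadjusted p under 0.05.

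The recomputed list criteria with adjusted p gave 83 probe sets in A549 and 12 in Calu-6. Not run were 1 probe set or the mean of probe sets per gene, a filter on dim genes and a trended prior, since the table used names few probe sets and holds no levels, and camera or fry on the fixed lists. Signal over background could not be assessed from centred values.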

Other observations

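The tests of the A549 list in Calu-6 were chosen after the data had been examined, as were the genes named in this part.

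In Calu-6 other genes, picked after their values were seen and from no fixed list, rose at 0.003 puffs/ml. UBE2L6, the conjugating enzyme for ISG15, rose by 1.72 on the log2 scale, TLR3, a sensor of double-stranded RNA, by 1.58, PARP14, an ADP-ribosyltransferase, by 1.5, and APOL2, an apolipoprotein L, by 1.02. In A549 the same genes were at 0.30, 0.30, 0.56 and 0.00, and the differences between the lines passed the test for each of the 4. Without Calu-6 TSC 0.003 replicate 3 the adjusted p of APOL2 in Calu-6 was 0.127. These genes are known to be inducible by interferon, but the list of interferon-stimulated genes fixed in advance had 0 calls in Calu-6, so no shared response is claimed.

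In A549 other genes picked after their values were seen fell at 0.003 puffs/ml, with 1 called probe set given for each; of the others, 1 of VCAN (adjusted p = 0.139) and 1 of JAG1 (adjusted p = 0.0832) did not pass. IGFBP3, which binds insulin-like growth factors, changed by -2.29, VEGFC, a growth factor of lymphatic vessels, by -2.28, VCAN, the proteoglycan versican, by -2.25, and TFF1, a mucosal trefoil peptide, by -2.57. The receptor NOTCH3 changed by -1.66 and JAG1, a Notch ligand, by -1.55. In Calu-6 the values were -0.31, -0.09, -0.69, -0.46, -0.24 and -0.15 in the same order. For all of these but JAG1 untreated Calu-6 lay over 2 log2 units under untreated A549, and signal over background could not be assessed, so whether a fall there was measurable stays open.

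A first hypothesis was that the genes changed in A549 move the same way in Calu-6. The 73 risen genes of the A549 list leaned upward in Calu-6, with 45 higher and 28 lower, 9 called higher, a median of 0.10 and a camera p of 3.03e-08 (p = 0.00536 with an estimated correlation, fry p = 0.00116). The 144 fallen genes did not lean, with 61 higher and 83 lower, 4 called higher and 3 called lower, a median of -0.07 and a camera p of 0.787 in the upward direction, opposite in sign to the median (p = 0.838 with an estimated correlation, fry p = 0.522). The risen genes may thus share part of their response, while for the fallen genes, 71 of them over 2 log2 units lower in untreated Calu-6, the question stays open. The reverse test was not made, because 31 of the 34 probe sets in the Calu-6 list had the same sign in A549, against 145 of the other 245 that met its stated criteria, so that list is not independent of A549.

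Another hypothesis was that genes known to respond to cyclic AMP through CREB fall in both lines. The 11 genes were picked from the falls of the A549 list, so their values in A549 (9 called lower, median -1.99) restate that choice and test nothing there. Among them were SGK1, a kinase (-2.37), NTS (-2.13), INSL4 (-2.16), PDK4, a mitochondrial kinase (-1.99), and the nuclear receptors NR4A2 (-1.82) and NR4A1 (-1.60). PPARGC1A, a coactivator, changed by -0.99 there, with an adjusted p of 0.0799 without A549 TSC 0.003 replicate 2. PDE4B (-1.23, adjusted p = 0.0720) and CHGB (-1.12, adjusted p = 0.0693) did not pass in A549. In Calu-6, 7 were lower and 4 higher, the median was -0.19 with quartiles of -0.27 and 0.06, 1 was called (PTGS2, higher) and the camera p was 0.998. The difference between the lines passed for 8 of the 11, and 4 were over 2 log2 units lower in untreated Calu-6 than in untreated A549. The test in Calu-6 thus leaves open whether lower CREB-regulated transcription applies there, and it was not tested in A549.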
